A study of Mus musculus with 5 samples.

How the data were processed

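Single-cell RNA sequencing of hippocampus from mouse pups at postnatal day 1 was analysed in 5 droplet libraries, 3 from wild-type and 2 from Trem2 knockout animals, each made from 2 pooled pups. Per the labels' protocols, the tissue was dissociated with papain and the libraries were made with a droplet kit that reads the 3' end of transcripts and tags each molecule with a unique molecular identifier (UMI). The deposited values are counts of UMIs per gene and cell barcode, whole numbers that were not normalised, for 32285 features. Per the submitters' processing notes Cell Ranger 6.1 was used with the mouse build mm10, and per the file headers the matrices were written by version 6.1.1. The annotation release behind the features is not given in the sources used here. Positions were taken from GENCODE mouse release M21 on the same build, in which 32158 features had a position.

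The files held 40345 barcodes, from 6512 in wild-type replicate 2 to 10582 in wild-type replicate 3. Cells were kept with at least 500 genes, at least 1000 UMIs and at most 15% mitochondrial UMIs. Doublets were scored per library with Scrublet as implemented in scanpy 1.11.5, at an expected rate of 0.8% per 1000 barcodes. The automatic threshold marked 1.97% of cells in wild-type replicate 1 and 4.33% in wild-type replicate 3. It marked under 0.5% in the other 3 libraries, where the cells with the highest scores were removed up to the expected number instead. This left 29062 cells. Counts were log-normalised, 2000 variable genes and 30 principal components were taken, and a graph of 15 neighbours was clustered with leidenalg 0.10.2 at a resolution of 1, with further clustering inside broad groups. Clusters were named from marker genes fixed before the data were examined, and a name ending in "like" marks such a class. The clusters that met no class held 2070 cells and stayed unnamed, among them a cluster of low-RNA cells with microglial genes. No cell annotation by the authors was used, so the classes are rebuilt ones.

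The library was the replicate. Raw counts were summed per library and class and tested with edgeR 4.0.16 (quasi-likelihood test, TMM factors, its filter on low counts, genotype as the only term, 3 residual degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. Classes with at least 20 cells in every library were tested, except the excitatory neurons of no named field, which were tested only within all excitatory neurons. Microglia-like cells were tested by design although the smallest library held 7. The difference between the genotype effects in CA1-like and CA3-like neurons was tested in 1 model with the library as a block. The 26 gene lists fixed beforehand were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01 where at least 5 members were measured, and fry and an estimated correlation were alternatives. Log2 scores of a list are the mean log2 CPM (counts scaled to equal library totals) of its members with a prior count of 2. Class shares, cell quality and list scores were compared by two-sided exact permutation tests over the 10 assignments of 5 libraries to groups of 3 and 2, for which the smallest p is 0.1.

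Genes were named by a rule set before the data were examined. It took Trem2, up to 8 genes per direction with the largest change among those that passed with a mean of at least 20 counts per library and groups that did not overlap, up to 3 by smallest p where fewer than 3 passed, and up to 4 members of each list by smallest p. Sex-linked genes and unnamed gene models were left out of the largest changes. Genes named outside this rule are said to be so.

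The test was tried on simulated counts with 200 changed genes. At a true change of 2-fold it recovered 80.0% of changed genes in CA1-like neurons, 74.2% in CA3-like neurons and 71.6% in all excitatory neurons, but 13.3% in microglia-like cells. At 1.5-fold the shares were 40.3%, 40.3%, 36.4% and 0%. These shares hold for 200 genes that change at once. With fewer changed genes the adjustment is stricter, so they overstate the recovery of a gene that changes alone. In the same simulations, which mixed 3 sizes of change, 7, 10, 10 and 4 unchanged genes were called. In a second simulation, with genes independent of each other, the complex I list was shifted by 0.3. With an estimated correlation its adjusted p was 0.0983 in CA1-like, 0.0336 in CA3-like and 0.0532 in all excitatory neurons and 0.941 in microglia-like cells. A call lost with an estimated correlation therefore does not show that a list is unchanged. Alternatives covered DESeq2 1.42.0, other size factors, no filter on low counts, the replicate number as a block, the number of male pups as a covariate, other limits on cells, doublets kept, a Leiden resolution of 2, thinned libraries and each library left out in turn. The block leaves fewer residual degrees of freedom than the main fit. In it wild-type replicate 1, the only library of its number, adds nothing to the genotype effect. Further alternatives were added after the data were seen. The closing section gives their effect. Python 3.11.15 and R 4.3.3 were used.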

Results

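Gene expression was measured by single-cell RNA sequencing in the newborn hippocampus of wild-type and Trem2 knockout mice. Trem2 is a lipid-sensing receptor that microglia carry on their surface. The title of the study names neuronal bioenergetics during development as its question, so transcripts of energy metabolism in pyramidal neurons of the hippocampal fields CA1 and CA3 were compared first. There were 3 wild-type libraries, numbered 1, 2 and 3, and 2 knockout libraries, numbered 2 and 3, each pooled from 2 pups at postnatal day 1. The total was 70357862, 60024793 and 91205882 UMIs in the wild-type libraries and 66984325 and 69010249 in the knockout libraries, with a median of 6871 to 7688 UMIs per barcode. After filtering, 6234, 4427 and 8113 wild-type cells and 5142 and 5146 knockout cells remained. The descriptions give males only for the libraries numbered 2 and 1 male and 1 female for the rest, while another label gives both sexes for every library. In microglia-like cells Xist, a transcript of female cells, was at 816 and 631 CPM in wild-type replicates 1 and 3. It was at 0 in wild-type replicate 2 and knockout replicate 2, which argues against both sexes in the libraries numbered 2.

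Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147 on the plus strand, mm10) was lower in knockout microglia-like cells. Its level in CPM (counts scaled to equal totals of the class) was 1406, 1562 and 1279 in the wild-type libraries and 61.07 and 139.9 in the knockout libraries, a mean of 1416 ± 141.8 (SD, n = 3) against 100.5 ± 55.74 (SD, n = 2). The log2 fold change was -4.22 (SE 0.355, adjusted p = 7.16e-06 by edgeR). Border macrophage-like cells held 276.3 ± 25.17 against 36.74 ± 34.12 CPM. In all excitatory neurons, which should lack the gene, 20 Trem2 UMIs were counted in the wild type and 1 in the knockout. The deleted part of the gene is not given in the labels, and 3' reads outside a deletion do not check it.

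**Figure D1:**
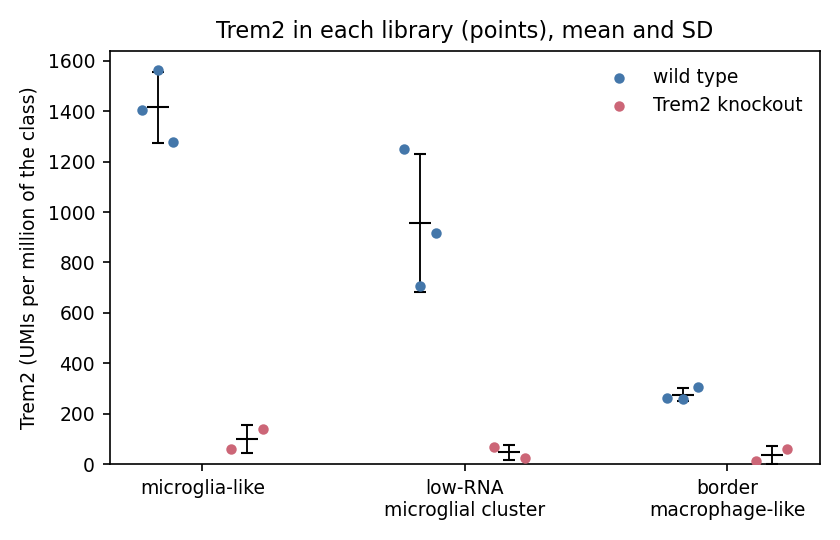
Trem2 level in CPM of the class (vertical axis, from 0) in microglia-like cells, the low-RNA microglial cluster and border macrophage-like cells, with a point per library and the mean and SD of 3 wild-type and 2 knockout libraries. In microglia-like cells the wild-type libraries lie between 1279 and 1562 and the knockout libraries at 61.07 and 139.9.

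In microglia-like cells, 2 of 6042 genes passed the threshold, both lower in the knockout. Besides Trem2 this was Cxcl10, an interferon-induced chemokine, at 241 ± 87.1 (SD, n = 3) against 17.8 ± 2.59 (SD, n = 2) CPM, a log2 fold change of -3.76 (SE 0.517, adjusted p = 0.00398 by edgeR) with every knockout library below every wild-type library. In knockout replicate 3 the Cxcl10 value of 19.7 CPM rests on few UMIs, since 7 Trem2 UMIs came to 139.9 CPM there. The small knockout SD is therefore no measure of precision. Without knockout replicate 2 the Cxcl10 call was lost (-3.54, adjusted p = 0.144). The next genes by p did not pass: the cell cycle inhibitor Cdkn1a at -1.57, the apolipoprotein Apoc1 at -2.15 and the chemokine Cxcl2 at -2.81, and on the other side As3mt at 1.07, Rfc2 at 0.93 and Ift20 at 0.88. Of the microglial lists, the homeostatic list had 7 members higher and 9 lower (median log2 fold change -0.0391, adjusted p = 0.867 by camera), the damage-associated list 11 and 13 (-0.062, 0.544), the complement and phagocytosis list 7 and 9 (-0.00153, 0.875, with the test pointing up) and the lysosomal list 10 and 14 (-0.0543, 0.867). The knockout libraries stood apart in the mean log2 level of the damage-associated list, at 9.332 in replicate 2 and 8.19 in replicate 3. The wild-type level was 9.297 ± 0.2436 (SD, n = 3). P2ry12, a purinergic receptor, was at -0.30 (SE 0.27) and Apoe at -0.30 (SE 0.23), neither past the test.

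The list of dividing-cell genes was lower in knockout microglia-like cells, with 6 of 8 members below 0 and a median of -0.30 (adjusted p = 0.00303 by camera). The list of immediate early genes, which respond to dissociation, was lower with 17 of 21 members below 0 and a median of -0.48 (adjusted p = 0.0143). With an estimated correlation the adjusted p was 0.956 for both, and 0 members of either list passed when adjusted over the list alone. Fos was at -0.80 (SE 0.298), Jun at -0.76 (SE 0.316), Top2a at -0.73 (SE 0.473) and Mki67 at -0.72 (SE 0.477). The dividing-cell median was -0.0182 (adjusted p = 0.8) without knockout replicate 3 and -3.04 (1.05e-08) without knockout replicate 2, and the call was lost without wild-type replicate 1 (-0.143, 0.0507). The immediate early call was lost without wild-type replicate 1 (-0.27, 0.829) and without knockout replicate 2 (-0.195, 0.123, with the test pointing up), and the median was -0.753 without knockout replicate 3. At a mitochondrial limit of 5% the dividing-cell list was called in the opposite direction (0.583, adjusted p = 0.000604), and its call was lost with the low-RNA microglial cluster (0.00998, 0.374) and with the replicate number as a block (-0.282, 0.0647). The immediate early call was lost with that block (-0.313, adjusted p = 0.44), with the number of males as a covariate (-0.356, 0.341) and in libraries thinned to the lowest total (0.0466, 0.968). The microglia-like class held 96, 50 and 17 wild-type cells and 35 and 7 knockout cells, and the number of genes past the threshold was 17 without knockout replicate 3 and 9 without knockout replicate 2.

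In CA1-like neurons, no oxidative phosphorylation transcript passed the test and no list of them was called. The 36 nuclear-encoded subunits of complex I had a median log2 fold change of -0.0131 and a mean of 0.00335, with 16 higher and 20 lower and the test pointing up (adjusted p = 0.813 by camera). The median was -0.0268 over 25 subunits of complexes II to IV, -0.0319 over 17 subunits of ATP synthase and 0.0798 over 13 mitochondrially encoded genes, each with an adjusted p of 0.813. None of these 4 lists had a member that passed when adjusted over the list alone. The mean log2 level of the complex I list was 7.783 ± 0.02032 (SD, n = 3) in the wild type and 7.787 ± 0.07278 (SD, n = 2) in the knockout (exact permutation p = 1). The complex I subunit Ndufs3 was at 0.20 (SE 0.0984) and the cytochrome oxidase subunit Cox8a at -0.16 (SE 0.0951). The tricarboxylic acid cycle list had a median of 0.0026 (adjusted p = 0.813), glycolysis -0.0738 (0.541), and mitochondrial biogenesis and dynamics 0.0547 (0.813, mean -0.00762, test pointing up), where Ppargc1a, a coactivator of mitochondrial biogenesis, was at -0.34 (SE 0.195).

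**Figure D2:**
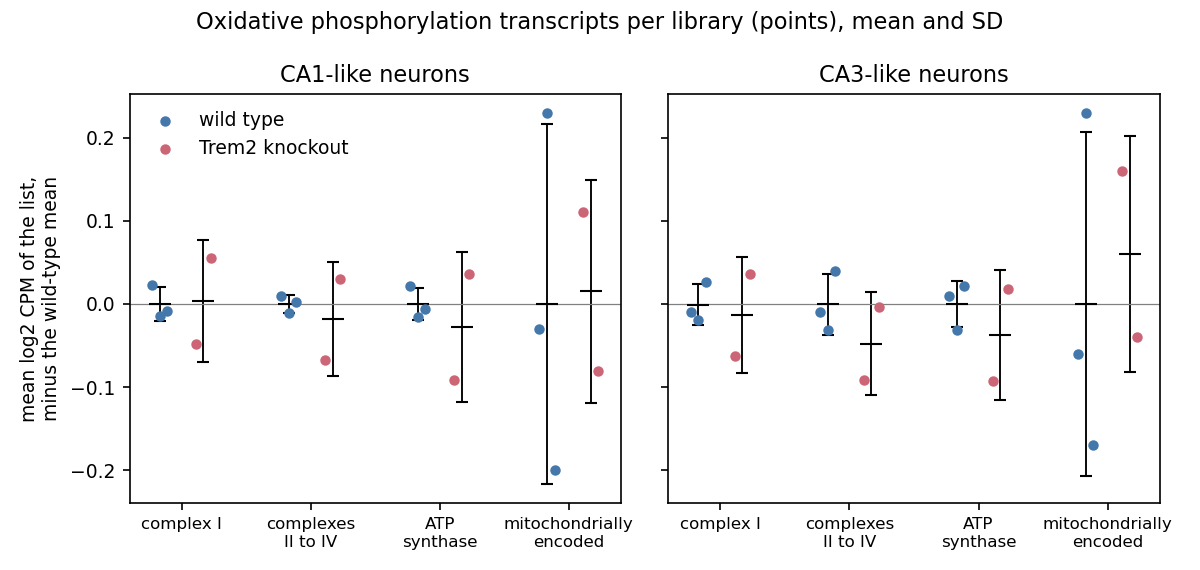
Mean log2 CPM of 4 oxidative phosphorylation lists in CA1-like and CA3-like neurons, each minus its wild-type mean (vertical axis), with a point per library and the mean and SD of 3 wild-type and 2 knockout libraries. In every list the ranges of the wild-type and knockout points overlap, and the exact permutation p for complex I in CA1-like neurons was 1.

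By edgeR 0 of 12082 genes passed in CA1-like neurons, with 511 at an unadjusted p under 0.05 (224 higher and 287 lower), but 16 with no filter on low counts, and DESeq2 called 1. That gene was Mrps10, a subunit of the mitochondrial ribosome (ENSMUSG00000034729, chromosome 17, 47368887 to 47381417), at 43.1 ± 6.45 (SD, n = 3) against 83.4 ± 0.611 (SD, n = 2) CPM, a log2 fold change of 0.92 (SE 0.134, adjusted p = 0.097 by edgeR and 0.00241 by DESeq2). Without wild-type replicate 2 edgeR called it as well (0.86, adjusted p = 0.0332). Mrps10 lies in the neighbourhood of Trem2, and its neighbours Mea1 and Mrpl2 were at -0.43 (SE 0.117) and 0.31 (SE 0.147). The other genes nearest the threshold did not pass: the cold-inducible RNA-binding protein Cirbp at 0.41, Ttc28 at 0.43, the vesicle fusion ATPase Nsf at -0.58, the thyroid hormone-binding Crym at -0.41 and the teneurin Tenm3 at -0.73.

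Cytosolic ribosomal genes were higher as a list in knockout CA1-like neurons, with 63 of 80 above 0 and a median log2 fold change of 0.0951 (adjusted p = 5.11e-05 by camera). Presynaptic genes were lower as a list, with 19 of 24 below 0 and a median of -0.12 (adjusted p = 0.0085). With an estimated correlation the adjusted p was 0.805 and 0.799, and 0 members of either list passed when adjusted over the list alone. In the mean log2 level of each list per library the groups overlapped (exact permutation p = 0.4 for the ribosomal and 0.3 for the presynaptic list). Among the members were Rpl13a at 0.23 (SE 0.0846) and Rplp0 at 0.20 (SE 0.0861), the vesicle protein Sv2b at -0.71 (SE 0.193), Nrxn3 at -0.38 (SE 0.168) and, against the direction of the list, Syt4 at 0.28 (SE 0.0911). The clusters of the class were filled unequally: its cluster 5 held 38.2, 26.7 and 45.5% of wild-type and 56.5 and 47.1% of knockout CA1-like cells, and its cluster 10 held 29.3, 40.5 and 18.9% against 19.1 and 17.8%. The ribosomal call was lost without wild-type replicate 2 (0.0539, adjusted p = 0.0852), without knockout replicate 3 (0.0624, 0.3) and at a mitochondrial limit of 5% (0.0156, 0.877). The presynaptic call was lost without wild-type replicate 1 (-0.132, 0.0567), without knockout replicate 2 (-0.0168, 0.634), at that limit (-0.0537, 0.349) and with the replicate number as a block (-0.105, 0.0566), and the median was -0.244 without knockout replicate 3.

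In CA3-like neurons no energy list was called either. The median log2 fold change was -0.000827 for complex I (18 higher and 18 lower, adjusted p = 0.934 by camera), -0.0661 for complexes II to IV (8 and 17, 0.262), -0.0176 for ATP synthase (7 and 10, 0.56) and 0.145 for mitochondrially encoded genes (8 and 5, 0.325), and 0 members passed when adjusted over the list alone. The mean log2 level of the complex I list was 7.785 ± 0.02448 (SD, n = 3) against 7.772 ± 0.07004 (SD, n = 2). By edgeR 0 of 13518 genes passed, with 519 at an unadjusted p under 0.05, but 68 with the replicate number as a block, 32 with no filter on low counts and 10 with the number of males as a covariate. DESeq2 called 1, again Mrps10 (0.75, adjusted p = 0.831 by edgeR and 0.0142 by DESeq2), which edgeR called with that block (0.673, 0.000294) and that covariate (0.747, 0.0314). Without knockout replicate 2 edgeR called 1 gene, the interneuron peptide Sst, which is named here after its value was seen. The other genes nearest the threshold did not pass: the transcription factor Tshz1 at 0.90, the contactin Cntn5 at 0.85, the glutamate transporter Slc1a3 at -0.98, Btaf1 at -0.77 and Sv2b at -0.77. The median UMIs per cell were 14140 ± 1364 (SD, n = 3) against 16540 ± 894.5 (SD, n = 2) without overlap (exact permutation p = 0.2). No list was called; the integrated stress response was nearest, with 9 of 13 members above 0 (median 0.0976, adjusted p = 0.0558).

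Over all excitatory neurons 5 lists were called. Genes of the integrated stress response were higher, with 11 of 14 above 0 and a median of 0.18 (adjusted p = 0.0125 by camera), and 1 member, Atf4, its central transcription factor, passed when adjusted over the list alone (0.36, SE 0.082, 72.6 ± 0.99 against 92.9 ± 0.192 CPM). Cholesterol synthesis genes were higher with 17 of 19 above 0 and a median of 0.0454 (adjusted p = 0.0373), but the groups overlapped in their mean log2 level (exact permutation p = 0.6). Lower lists were complement and phagocytosis with 8 of 10 below 0 and a median of -0.44 (0.0373) and interferon response with 7 of 8 below 0 and a median of -0.23 (0.0373). The interferon list lay near the floor in these neurons (1.091 against 0.7632 log2 CPM). So did the complement list, which holds genes typical of microglia (0.7532 against 0.3826 log2 CPM). Other microglial lists were lower too without being called. Their medians were -0.102 for the homeostatic list (adjusted p = 0.262) and -0.104 for the damage-associated list (0.0874). In the mean log2 level of each, both knockout libraries lay below every wild-type library. Whether the neurons themselves changed was not tested. Erythroid transcripts were higher with 5 of 5 above 0 (median 0.33, adjusted p = 0.0329). In their mean log2 level wild-type replicate 3 was highest, at 4.1 against 4.044 and 2.459 in the knockout libraries (exact permutation p = 0.4). Of the Hbb-bs UMIs of dentate granule-like neurons, 1 droplet held 99.8% in knockout replicate 2 and 94.4% in knockout replicate 3. In CA3-like neurons of wild-type replicate 3 the share was 97.8%. With an estimated correlation the adjusted p was 0.588 for the erythroid list and 0.556 for the other 4 lists. Each of these calls was lost in some fit without a single library. For the stress response these were the fits without wild-type replicate 3 (0.154, adjusted p = 0.112) and knockout replicate 2 (0.0837, 0.0538). For cholesterol synthesis they were those without wild-type replicate 2 (0.0313, 0.59) and knockout replicate 3 (0.000354, 0.293), while the median was 0.114, 0.0939 and 0.106 without wild-type replicate 1, wild-type replicate 3 and knockout replicate 2. The complement call was lost without wild-type replicate 1 (-0.334, 0.31) and 2 (-0.247, 0.258), and the erythroid call without these and knockout replicate 2 (-0.0753, -0.084 and -0.248, with the test pointing up in each), and its median was 0.951 without knockout replicate 3. The interferon call was lost without wild-type replicate 1, 2 or 3 or knockout replicate 2 (adjusted p = 0.107, 0.0612, 0.177 and 0.61), and its median was -0.121 without wild-type replicate 3 and -0.365 without knockout replicate 3. In libraries thinned to the lowest total of the class, which does not equalise depth per cell, the calls of the stress response (0.0776, adjusted p = 0.0595), complement (-0.228, 0.272), cholesterol synthesis (0.0398, 0.0683) and interferon response (-0.222, 0.0592) were lost. At a mitochondrial limit of 5% these were lost as well (0.0839, -0.17, 0.0684 and -0.0727, adjusted p = 0.239, 0.605, 0.153 and 0.802). With the replicate number as a block the complement, interferon and erythroid calls were lost (adjusted p = 0.147, 0.147 and 0.141). The interferon call was also lost with the number of males as a covariate (0.136), the cholesterol call with doublets kept (0.0506) and the erythroid call with no mitochondrial limit (-0.0629, 0.183). The groups did not overlap in depth per cell: an excitatory neuron held a median of 8670 ± 356.8 UMIs (SD, n = 3) in the wild type and 10220 ± 1299 (SD, n = 2) in the knockout, and 3248 ± 73.94 against 3571 ± 292.7 genes, with every knockout library above every wild-type library in both (exact permutation p = 0.1 for each). Whether depth per cell bears on these lists was not tested. By edgeR 0 of 15296 genes passed, with 408 at an unadjusted p under 0.05, but 36 with the replicate number as a block, 13 with no filter on low counts and 1 with the number of males as a covariate. DESeq2 called Mrps10 (0.76, SE 0.0929, adjusted p = 0.132 by edgeR and 4.1e-07 by DESeq2). With that block (0.724, adjusted p = 0.000373) and that covariate (0.766, 0.0173) edgeR called it too. Without wild-type replicate 2 it called Mrps10 (0.76, adjusted p = 0.02) and Arl6ip5 (-0.81, adjusted p = 0.02).

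**Figure D3:**
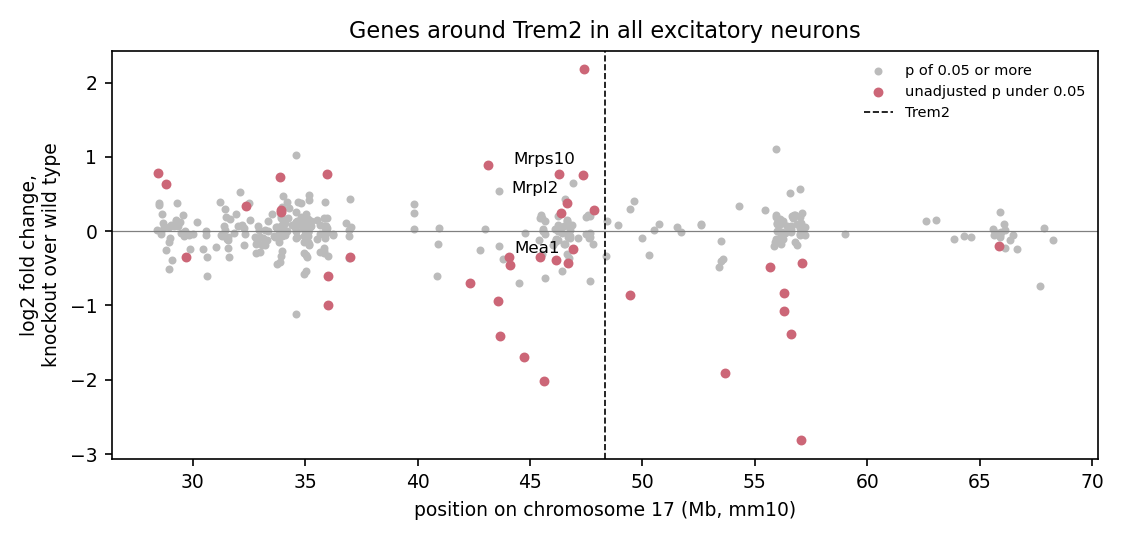
Log2 fold change of knockout over wild type in all excitatory neurons (vertical axis) by position on chromosome 17 in Mb of mm10 (horizontal axis), with a point per tested gene within 20 Mb of Trem2 (dashed line) and genes at an unadjusted p under 0.05 in red. Within 2.5 Mb of Trem2 10 of 60 genes had such a p, among them Mrps10 at 0.76.

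The genotype effect differed between CA1-like and CA3-like neurons for 4 of 13184 genes by edgeR, with 565 at an unadjusted p under 0.05, and DESeq2 called 0. Crym was lower by -0.43 in the CA1-like effect relative to the CA3-like effect (SE 0.0609, adjusted p = 0.00313), from effects of -0.41 and 0.011, and it was also among the marker genes used to name CA1-like clusters. Hmgb3, a chromatin protein, was at -0.55 (SE 0.09, adjusted p = 0.0136), from effects of -0.26 and 0.28. Without CA3-like cluster 17, which held 4.02, 2.73 and 5.22% of wild-type and 7.97 and 7.83% of knockout cells of its class, the Hmgb3 difference was -0.278 (adjusted p = 1). Haemoglobin transcripts were the others, Hbb-bs at 4.38 (SE 0.471, adjusted p = 6.89e-05) and Hba-a1 at 4.20 (SE 0.633, adjusted p = 0.00539). The Hbb-bs call was lost without knockout replicate 3 (2.39, adjusted p = 1), and the Hba-a1 call without wild-type replicate 3 (3.79, 0.0973) and knockout replicate 3 (-3.3, 1). The Crym call was lost without wild-type replicate 1 (-0.404, adjusted p = 0.32) and knockout replicate 2 (-0.346, 0.427) and at a Leiden resolution of 2 (-0.378, 0.154). The Hmgb3 call was lost without wild-type replicate 1 (-0.473, adjusted p = 0.436), knockout replicate 2 (-0.552, 0.235) and knockout replicate 3 (-0.558, 0.159) and with no mitochondrial limit (-0.536, 0.0616). At a mitochondrial limit of 5% all 4 calls were lost. The haemoglobin calls were lost with doublets kept (adjusted p = 1 and 0.985) and with top-score doublets (0.0532 and 0.713). The number of genes past the threshold was 2 without wild-type replicate 1 and 59 without wild-type replicate 3. The cytosolic ribosomal list had a higher effect in CA1-like neurons for 75 of 80 members (median 0.0621, adjusted p = 4.48e-07 by camera, adjusted p = 0.994 with an estimated correlation), and 0 members passed when adjusted over the list alone. At a mitochondrial limit of 5% that call was lost (0.00169, adjusted p = 0.937, with the test pointing down). No energy list was called, and the median difference for complex I was 0.00208 (adjusted p = 0.925).

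Among 11 further classes, 8 genes passed by edgeR and 16 by DESeq2. By edgeR 950 passed with the replicate number as a block, 466 with no filter on low counts and 142 with the number of males as a covariate. It called 3, 56 and 20 without wild-type replicate 1, 2 and 3 and 31 and 19 without knockout replicate 2 and 3. In inhibitory neuron-like cells 1 gene was higher in the knockout, which is not named here, and 3 were lower. The lower genes were the transcription factors Foxp2 at -2.50 (adjusted p = 0.0311) and Meis2 at -1.71 (0.000294) and the cyclin Ccnd2 at -1.32 (0.0311). The class pools 2 clusters that were filled unequally, its cluster 15 holding 43.2, 41.2 and 42.2% of wild-type and 36.3 and 35.4% of knockout cells. No test was run within a cluster. These 3 calls were lost without wild-type replicate 1, with an adjusted p of 0.424, 0.0781 and 0.252, and at a mitochondrial limit of 5% or with doublets kept. Foxp2 lost its call without wild-type replicate 3 (adjusted p = 0.0888) and by DESeq2 (0.0618) as well, and Foxp2 and Ccnd2 with no mitochondrial limit (0.0676 for each). C1ql1, a synaptic organiser, was higher in Cajal-Retzius-like neurons at 0.97 (adjusted p = 0.00372) and lost its call without wild-type replicate 1 (0.163), knockout replicate 2 (0.0846) and knockout replicate 3 (0.215) and at the 5% limit (0.0709). Chgb, a secretory granule protein, was higher in choroid plexus-like cells at 1.60 (adjusted p = 0.00955) and lost its call without wild-type replicate 3 (0.109), knockout replicate 2 (0.344) and knockout replicate 3 (0.31), with doublets kept (1.43, 0.23), at a Leiden resolution of 2 (1.38, 0.0876) and at the 5% limit (1.08, 0.805). Calls were also made for the haemoglobin transcripts Hbb-bs at 5.44 and Hbb-bt at 7.11 in dentate granule-like neurons, lost without wild-type replicate 1 (adjusted p = 0.361 and 0.994) and for Hbb-bt also without wild-type replicates 2 (0.216) and 3 (0.102), while Hbb-bs lost its call at the 5% limit (7.18, 0.232).

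In radial glia or astrocyte-like cells 27 of 36 complex I genes (median -0.0456, adjusted p = 0.0267 by camera), 21 of 25 genes of complexes II to IV (-0.0922, 0.00313) and 17 of 17 ATP synthase genes (-0.063, 0.0267) were below 0. The adjusted p was 0.911 for all 3 lists with an estimated correlation, and 0 members passed when adjusted over the list alone. All 3 calls were lost without wild-type replicate 1 (medians -0.0304, -0.0767 and -0.044, adjusted p = 0.476, 0.346 and 0.404) and without knockout replicate 2 (-0.0875, -0.101 and -0.104, adjusted p = 0.0838, 0.0633 and 0.0801). Those of complex I and ATP synthase were also lost without wild-type replicate 2 (-0.0307 and -0.0422, both 0.255) and knockout replicate 3 (-0.0356 and -0.000119, both 0.217). Without wild-type replicate 3 the medians were -0.0975 for complex I and -0.123 for ATP synthase, and without knockout replicate 3 that of complexes II to IV was -0.0554. With the replicate number as a block all 3 calls were lost (adjusted p = 0.291, 0.15 and 0.225), as they were at a Leiden resolution of 2 (0.175, 0.0569 and 0.16), and those of complex I and ATP synthase also with doublets kept (both 0.104). Of the clusters of the class, cluster 19 held 9.69, 8.26 and 13.1% of wild-type and 14.8 and 20.2% of knockout cells. It is a low-RNA cluster, with a median UMI count of 0.23 times that of its library, and the lists were not tested without it. In inhibitory neuron-like cells 7 of 21 lists were called by camera, 5 higher and 2 lower in the knockout. Complex I and the mitochondrial ribosome were among the 7, and both medians turned below 0 at a mitochondrial limit of 5%. None of the 53 list calls over all classes held with an estimated correlation. That test also missed a simulated shift of 0.3 in CA1-like, all excitatory and microglia-like cells.

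Excitatory neurons made up 33.94 ± 5.881% (SD, n = 3) of kept cells in the wild type and 43.25 ± 2.369% (SD, n = 2) in the knockout (exact permutation p = 0.2). CA3-like neurons made up 8.22 ± 2.028% against 12.05 ± 1.245% (exact permutation p = 0.2). Oligodendrocyte precursor-like cells made up 4.247 ± 0.8339% against 2.518 ± 0.01485% and fibroblast or meningeal-like cells 2.097 ± 0.2359% against 1.293 ± 0.01414%, each at the smallest p the design allows (exact permutation p = 0.1). Microglia-like cells made up 0.9595 ± 0.6813% against 0.4083 ± 0.3852% (exact permutation p = 0.4). The groups did not overlap in 4 of 18 classes, where chance gives 20%. The edgeR test on cell counts called 0 classes, with a smallest adjusted p of 0.501.

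**Figure D4:**
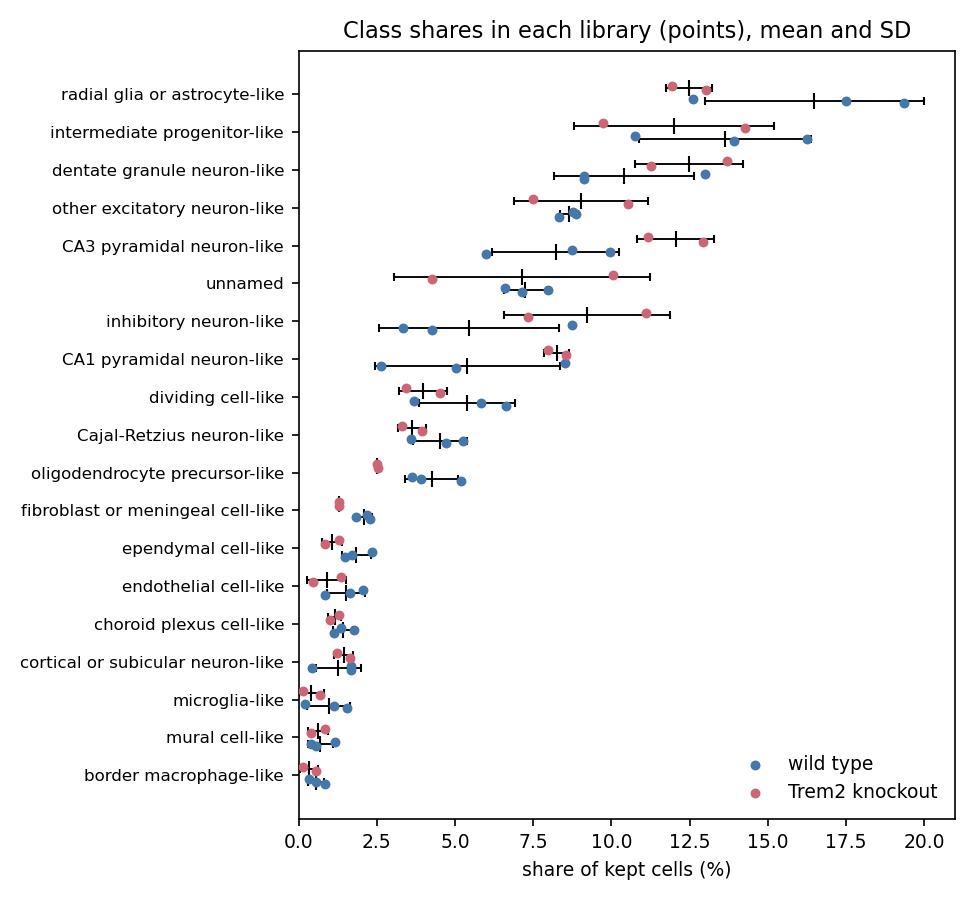
Share of kept cells in each class in percent (horizontal axis, from 0), with a point per library and the mean and SD of 3 wild-type and 2 knockout libraries. Oligodendrocyte precursor-like cells lie at a mean of 4.247% in the wild type and 2.518% in the knockout.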

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

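The tests on the chromosome 17 neighbourhood, on depth, on the top haemoglobin droplet and the random-draw comparison were chosen after the results were seen. Results stand here because the genotype effect differed between CA1-like and CA3-like neurons in a test of that difference: Hbb-bs (4.38, adjusted p = 6.89e-05 by edgeR), Hba-a1 (4.20, 0.00539), Crym (-0.431, 0.00313), Hmgb3 (-0.549, 0.0136) and the cytosolic ribosomal list (median 0.0621, adjusted p = 4.48e-07 by camera, 0.994 with an estimated correlation). Without CA3-like cluster 17 the Hmgb3 difference was -0.278 (adjusted p = 1).

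Haemoglobin transcripts differed between the genotypes in dentate granule-like neurons and between pyramidal fields. A change in most cells of a class is argued against by the distribution over droplets, since 97.8% of Hbb-bs UMIs of CA3-like neurons in wild-type replicate 3 lay in 1 droplet, as did 99.8 and 94.4% of those of dentate granule-like neurons in knockout replicates 2 and 3. Without droplets of 10 or more haemoglobin UMIs Hbb-bs was called by edgeR in 0 of 2 tests, at -0.449 (SE 0.47, adjusted p = 0.952) in dentate granule-like neurons and at 0.606 (SE 0.454, adjusted p = 1) between the fields, which for Hbb-bs is consistent with red cell RNA in single droplets. The other 2 of the 4 calls, Hbb-bt in dentate granule-like neurons and Hba-a1 between the fields, had too few counts left for a test, so this decides nothing for them.

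Cytosolic ribosomal genes were higher and presynaptic genes lower as lists in CA1-like neurons. A difference in the total UMIs of the class per library is argued against for the ribosomal list, since libraries thinned to the lowest total gave a ribosomal adjusted p of 4.25e-05 and a median of 0.0893. Thinning does not equalise depth per cell, whose effect was not tested. With 31 cells from each of the clusters in every library, the ribosomal median over 20 draws was 0.0256 (range -0.0353 to 0.0892), against 0.0783 (0.0293 to 0.127) in random draws of as many cells, and the call was made in 1 and 15 of the draws. The presynaptic median was -0.00972 (range -0.151 to 0.0409) against -0.124 (-0.217 to -0.0257), but it was still -0.0928 (adjusted p = 0.194 by camera) in cluster 5 alone. In cluster 10 alone the presynaptic test pointed the other way. Other shares of the CA1-like clusters may account for most of the ribosomal shift, while for the presynaptic list the values go both ways, and whether the genotype or the dissection set those shares stays open.

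Genes beside Trem2 differed in excitatory neurons: 10 of 60 genes within 2.5 Mb (16.7%) had an unadjusted p under 0.05. A shift of the whole chromosome is argued against by genes beyond 20 Mb, of which 2.68% had such a p (upper exact bound 4.88), beside 8.83% at 2.5 to 20 Mb and 2.48% on other chromosomes. Of 13394 windows of 60 consecutive genes on other chromosomes, 0% held as many, and the most in any was 8. These values go with sequence linked to the targeted locus, such as flanking strain DNA. The list of Trem2 neighbours fixed beforehand was not called by camera in excitatory neurons. Its mean log2 level was 3.376 ± 0.101 (SD, n = 3) against 3.442 ± 0.07304 (SD, n = 2), with an exact permutation p of 0.5. Such a test looks for a shared direction, while Mrps10 was higher and Mea1 lower. Mrps10 was higher in the knockout in 13 of 13 classes other than microglia-like cells and the pooled neurons. An action of Trem2 loss on these genes cannot be told apart from linked sequence, because every knockout library carries both.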

How the results depend on the processing

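The fits on single clusters, without CA3-like cluster 17, with the low-RNA microglial cluster, without haemoglobin-rich cells, without both libraries numbered 3 and with top-score doublets were chosen after the data were seen. Of 3241 values of gene lists under alternatives 2745 kept their direction and side of the threshold, 336 fell short of it, 86 passed it, 26 turned and 48 counts of called lists moved, and of 10302 values of named genes these were 10019, 59, 219 and 5. All 494 values of shares and cell quality kept within the spread, but no such test could pass. The cause was not tested for the values below. Counts of genes past the threshold in CA1-like, CA3-like and all excitatory neurons, the other classes and the difference between pyramidal fields were 1, 1, 1, 16 and 0 by DESeq2, and 16, 32, 13, 466 and 37 with no filter on low counts, where microglia-like cells gave 13 and lists 82. With the replicate number as a block they were 68 in CA3-like neurons, 36 in excitatory neurons, 4 in microglia-like cells and 950 in the other classes. That fit has fewer residual degrees of freedom. It moved the adjusted p of Trem2 in microglia-like cells from 7.16e-06 to 2.42e-32 by edgeR, at an SE of 0.355 and 0.337. The numbers are not known to pair the libraries: deviations of those numbered 2 and 3 correlated across genes at r = 0.457 and 0.312 in excitatory neurons, but wild-type replicate 1 with knockout replicate 3 reached 0.289, and the deviations of 2 knockout libraries mirror each other. The number of males as a covariate gave 10, 1 and 142 in CA3-like neurons, excitatory neurons and the other classes. A mitochondrial limit of 5% gave 10 in microglia-like cells, 3 in the other classes, with 0 of the 8 main calls among them, and 0 between the fields. Doublets kept gave 3 in the other classes. Top-score doublets, and the removal of haemoglobin-rich cells, each gave 2 between the fields. CA1-like cluster 10 alone gave 1, and microglia-like cells without both libraries numbered 3 gave 31. List calls numbered 0 with an estimated correlation and 2 by fry.

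Cells kept numbered 15838 at the 5% limit, 34020 with no limit, 27912 at 1000 genes, 30699 with doublets kept and 28297 with top-score doublets. Without a library in turn, genes past the threshold ranged from 0 to 1 in CA1-like and in CA3-like neurons, 0 to 2 in excitatory neurons, 2 to 17 in microglia-like cells, 3 to 56 in the other classes and 2 to 59 between the fields, list calls from 33 to 63, the Trem2 log2 fold change from -4.5 to -3.5, and shares and quality stayed at 0. With 1 knockout library left, it was assumed to vary like the wild-type libraries.

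The list tests below turned, and their medians are given. In CA1-like neurons the ribosomal median was -2.76e-05 and -0.00751 in clusters 5 and 10 alone. Medians that kept their sign while the test turned were -0.00339 for the presynaptic list in cluster 10 and, between the fields, 0.00169 for the ribosomal list at the 5% limit. In microglia-like cells complexes II to IV turned to -0.496 without knockout replicate 2 (highest 0.202, without knockout replicate 3), and ATP synthase to 0.219 with the low-RNA cluster. Mitochondrially encoded genes turned to -0.549 at the 5% limit, -0.0949 with the low-RNA cluster and -0.157 without both libraries numbered 3. The glycolysis test turned up from a median of 0.0104, to 0.417 without knockout replicate 3 (lowest -1.36, without knockout replicate 2) and 0.401 without both. At the 5% limit the ribosomal list turned to -0.346 and complement, whose median was below 0 already, to -0.621, and dividing-cell genes were called the other way at 0.583 (adjusted p = 0.000604). The test on dividing-cell genes also turned without knockout replicate 3 (median -0.0182, lowest -3.04 without knockout replicate 2) and without both (-0.0635), and that on immediate early genes without knockout replicate 2 (-0.195, lowest -0.753 without knockout replicate 3) and in thinned libraries (0.0466). The choroid ribosomal list was called the other way at 0.141 at the 5% limit (adjusted p = 0.00245) and 0.0808 with doublets kept (0.0336), and turned to 0.0178 without knockout replicate 3 (lowest -0.24, without knockout replicate 2) and 0.0169 with top-score doublets. The ependymal axon growth test turned with doublets kept (-0.0565, the median still below 0) and top-score doublets (0.0499). In inhibitory neurons complex I (-0.0121) and the mitochondrial ribosome (-0.0203), both called in the main fit, turned at the 5% limit. Hbb-bs in dentate neurons turned to -0.449 without haemoglobin-rich cells. Between the fields Hbb-bs, Hba-a1 and Hbb-bt turned to -1.2, -1.28 and -3.82 with doublets kept, and Hba-a1 to -3.3 without knockout replicate 3 (highest 4.55, without knockout replicate 2). Depth limits the microglia-like class, with 50037 UMIs from 7 cells in knockout replicate 3.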

Other observations

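Which lists and classes to describe here was chosen after their values were seen, while the members of the lists were fixed in the plan. Cholesterol synthesis genes were higher as a list in several neuronal classes of the knockout: 17 of 19 above 0 in Cajal-Retzius-like neurons (median 0.25, adjusted p = 9.11e-07 by camera), 18 of 19 in dentate granule-like neurons (0.31, 3.23e-06) and 14 of 19 in inhibitory neuron-like cells (0.11, 0.0316), while in ependymal-like cells 14 of 19 were below 0 (-0.12, 0.0367). With an estimated correlation the adjusted p was 0.229, 0.627, 0.661 and 0.793, and 0 members passed when adjusted over the list alone. The inhibitory and ependymal calls were also lost in thinned libraries (0.0844, adjusted p = 0.211, and -0.14, 0.124) with doublets kept (0.0782, 0.113, and -0.066, 0.445) and with top-score doublets (0.0971, 0.0682, and -0.0392, 0.572), the inhibitory call at a mitochondrial limit of 5% (0.0759, 0.306), with no such limit (0.0991, 0.0588) and at 1000 genes per cell (0.0979, 0.0591), and the ependymal call with the replicate number as a block (-0.076, 0.189), with the number of males as a covariate (-0.107, 0.07) and at a Leiden resolution of 2 (-0.143, 0.0549). The Cajal-Retzius call held without any single library, but depth per cell did not overlap between the groups in that class, with a median of 12600 ± 621 UMIs (SD, n = 3) against 13930 ± 236.5 (SD, n = 2) and 4132 ± 118.7 against 4357 ± 62.58 genes (exact permutation p = 0.2 for each). The clusters of the dentate class were filled unequally, its cluster 0 holding 75, 82.4 and 54.7% of wild-type and 58.4 and 41.7% of knockout cells, and its call was lost without knockout replicate 3 (0.0649, adjusted p = 0.151), with medians of 0.197 and 0.182 without wild-type replicates 1 and 2. The inhibitory call was lost without wild-type replicate 2 (0.0787, 0.175), wild-type replicate 3 (0.08, 0.28) and knockout replicate 3 (0.028, 0.121), with 0.171 and 0.0684 without wild-type replicate 1 and knockout replicate 2. The ependymal call was lost without wild-type replicate 1 (-0.116, 0.212) and knockout replicate 2 (-0.0808, 0.678), with -0.217 and -0.385 without wild-type replicate 3 and knockout replicate 3.

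In inhibitory neuron-like cells, whose clusters were filled unequally too, 18 of 20 immediate early genes were above 0 (median 0.30, adjusted p = 6.17e-10), and 3 passed when adjusted over the list alone. The adjusted p was 0.379 with an estimated correlation, and without wild-type replicate 3 the median was 0.609.

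Dividing-cell genes went different ways in different classes. In fibroblast or meningeal-like cells 8 of 8 were below 0 (median -2.05, adjusted p = 3.62e-36 by camera) and 8 passed when adjusted over the list alone, and in choroid plexus-like cells 8 of 8 were below 0 (-1.76, 1.57e-14) with 6 passing. In oligodendrocyte precursor-like cells 8 of 8 were above 0 (0.35, 1.2e-09) with 3 passing. With an estimated correlation the adjusted p was 0.368, 0.678 and 0.531, and these 3 calls held without any single library. The oligodendrocyte precursor-like class includes a dividing cluster that held 20.4, 12.7 and 16.9% of its wild-type and 21.5 and 21.7% of its knockout cells, and a small fibroblast or meningeal-like cluster held 13.4, 0 and 10.2% against 0 and 4.55%. No test was run within these clusters. Whether these effects differ between the classes was not tested.

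In microglia-like cells without knockout replicate 3, which held 7 of them, the genes past the threshold included the chemokines Cxcl2 at -4.42, Ccl4 at -1.95 and Ccl3 at -1.23. The cytokine Il1a at -1.74, Fosb at -2.34 and, in the other direction, Slpi at 2.22 were also among them. Slpi was at 4.82, 11.3 and 106 CPM in wild-type replicates 1, 2 and 3 and at 80.1 CPM in knockout replicate 2. The knockout value thus lay below that of wild-type replicate 3. The mean Slpi count of 15.5 was also under the minimum of the naming rule, so no rise in the knockout is read from it. Without knockout replicate 2 only Trem2 passed again. The genes past the threshold there held no chemokine and included Spp1 at -13.8, Fabp5 at -2.37, Csf1 at 1.92 and Klf2 at 1.61. Spp1 was at 0 CPM in the 7 cells of knockout replicate 3, so -13.8 is set by a count of 0 and is not a measured size. All were named after their values were seen. Ccl4 and Ccl3 were both among the top 10 genes of 4 of the 5 clusters of the class, which held 68.6% of its cells in knockout replicate 2 and 83.3, 66 and 94.1% in the wild-type libraries. Xist was also among the genes past the threshold without knockout replicate 3, and the remaining knockout library is described as male pups only.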
